A study of Mus musculus with 34 samples.

How the data were processed

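RNA sequencing libraries were made from heart and adipose tissue of C57BL/6J mice on 1 of 3 diets: a control diet, a high-fat, high-calorie diet (HFCD), or HFCD interrupted by cycles of a fasting mimicking diet (HFCD+FMD). The labels list 34 libraries. The deposited tables held columns for 27 of them, 14 of heart and 13 of adipose tissue, and these 27 were used. The 7 other libraries were not analysed here. All per-sample columns of these tables were used (0 left out). The labels name the tissue, the diet, the age and a replicate number, and only the design text, which speaks of 18 mice, says that libraries of 1 tissue came from separate animals. The p-values therefore measure the spread between libraries.

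According to the submitted protocol, total RNA was extracted with RNeasy columns, ribosomal RNA was removed with the KAPA RNA Hyper RiboErase HMR chemistry and the libraries were sequenced on an Illumina instrument. The processing notes name STAR 2.5.3, the mouse genome build mm10, R 3.5.3, edgeR and limma. The program that counted reads per gene and its annotation were not stated in the sources used here. The authors deposited whole-number read counts per gene, without normalization, for each tissue. The authors also deposited log2 CPM (counts scaled to a common library total) of a scaled library size with 0.5 added to each count. Each deposited adipose log2 column differed from the log2 CPM of the count table by 1 constant per library. In heart the deposited log2 values had in addition lost 1 term per gene that was shared within each of 3 sets of libraries, to within 9.8e-09. Set A held control replicates 2, 3 and 5 and HFCD replicates 1, 2, 3 and 4. Set B held control replicates 4 and 6 and HFCD+FMD replicate 1, and set C held HFCD+FMD replicates 2, 3 and 5 and HFCD replicate 5. What the sets stand for was not stated in the labels. Gene symbols were those of the deposited tables. For genes present only in the count tables (72 in heart and 63 in adipose tissue), and for coordinates and transcript lengths, the GENCODE M21 annotation of GRCm38 was used.

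Counts were analysed in R 4.3.3. Each tissue was fitted on its own with edgeR 4.0.16, all 3 diets in 1 model. Libraries were scaled with TMM and genes were kept by filterByExpr on diet, which left 13230 of 13238 genes in heart and 15112 of 15145 in adipose tissue. Diets were compared with the robust quasi-likelihood F-test, two-sided, and p-values were adjusted over all genes tested with the Benjamini-Hochberg procedure at a false discovery rate of 0.05. The heart model held the 3 library sets as a factor. In that model only HFCD replicate 5 (set C) and HFCD+FMD replicate 1 (set B) tie HFCD+FMD to the other diets, so a fit without either rests on the other alone. Values per diet are means of TMM-scaled CPM with their SD. Log2 fold changes come from the edgeR model with its SE, and log2 CPM values carry a prior count of 2. Of the 48 gene lists written beforehand, those with at least 5 genes tested were compared with limma camera (limma 3.58.1) on voom values with a preset inter-gene correlation of 0.01, and again with a correlation estimated for each list. No list passed in any comparison with the estimated correlation. Counts of list members at the same false discovery rate are given over all genes tested and adjusted over the list alone. The difference between tissues was tested as the tissue-by-diet interaction in a joint edgeR fit of the 27 libraries, without a set factor. The 34 libraries of the labels exceed the 18 mice, so some mice gave both tissues, but the labels do not tie libraries to animals, and this fit and its shuffles treated the tissues as independent. The share of genes that moved back under HFCD+FMD was set against 20 simulated data sets in which HFCD+FMD equalled HFCD. It was also recomputed with the HFCD libraries divided so that the compared contrasts shared none, and is given with its 95% exact binomial interval, which covers counting error only.

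The sample groups, the tests, the gene lists, the 13 heart and 18 adipose genes reported whatever their result, most alternatives to these choices and the rule for naming genes were fixed before the data were examined. Of the heart genes reported whatever their result, 1 is not reported here. That rule took, for each tissue and comparison, the genes that passed, had no predicted or clone name and a mean of at least 1 CPM in a compared diet. Of these it named the 10 largest rises, the 10 largest falls and up to 4 members with the smallest p of each list. Where fewer than 5 genes passed, it named the 5 with the smallest p as not passing. The genes and lists given in the text are a subset of that set, chosen after the values were seen. The alternatives tried were RLE scaling, DESeq2 1.42.0, voom with and without library quality weights, no low-count filter, a stricter one (1 CPM in 5 libraries), only the diets compared, age as a covariate, the deposited log2 values, no set factor and each library left out in turn. Alternatives added after the data were seen were set A alone, leaving out HFCD replicate 5, or replicates 3 and 5, of heart without a set factor, leaving out the mitochondrially encoded genes, and 2 treatments of a leftover ribosomal transcript, Gm15564, in adipose tissue.

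Total counts per library were 15604982 to 40831656 in adipose tissue and 16848195 to 47859170 in heart. No pair of libraries of 1 tissue and diet held identical counts: the chi-square statistic per gene between such libraries was 24.5 to 325 over 24 adipose pairs and 12.3 to 865 over 26 heart pairs. The fit was tested on simulated counts with the depth and spread of these libraries, in which 100 genes changed 2-fold and 100 changed 4-fold. In heart, 59, 33 and 40 of the 2-fold genes were called for HFCD versus control, HFCD+FMD versus HFCD and HFCD+FMD versus control, and 99, 93 and 93 of the 4-fold genes. In adipose tissue the numbers were 55, 60 and 52 at 2-fold and 90, 88 and 85 at 4-fold. Between 4 and 9 unchanged genes were called in each simulation.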

Results

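Gene expression was measured by RNA sequencing in heart and adipose tissue of mice aged 20 to 22 months on 1 of 3 diets. In the control diet 10% of the calories came from fat, and in HFCD 60% did. The HFCD+FMD mice ate HFCD and, every 4 weeks, a fasting mimicking diet for 5 days. From cycle 6 onward each of these fasts was followed by 2 days of control diet, and tissue was taken 4 days after the last of 11 cycles. Adipose libraries numbered 3 for control, 4 for HFCD and 6 for HFCD+FMD, with 15604982 to 28495331, 23523322 to 36688935 and 27868228 to 40831656 counts each. Heart libraries numbered 5 for control, 5 for HFCD and 4 for HFCD+FMD, with 16848195 to 33180337, 23707218 to 41712499 and 17050559 to 47859170 counts each.

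The first comparison, HFCD against control in adipose tissue (n = 4 and n = 3), asked what the high-fat diet changed. Genes that build fatty acids from carbohydrate were far lower under HFCD. Elovl6, which lengthens long-chain fatty acids, fell from 1125 ± 429 CPM in control to 19.3 ± 5.16 CPM in HFCD (SD; log2 fold change -5.87, SE 0.78, adjusted p = 0.000687). Acaca makes malonyl-CoA, from which fatty acids are built, and fell from 1001 ± 232 to 62.1 ± 4.8 CPM (log2 fold change -4.01, SE 0.59, adjusted p = 0.00119). Fasn, the fatty acid synthase itself, had a log2 fold change of -3.37 (SE 0.74, adjusted p = 0.00655), and the desaturase Scd1 fell from 104766 ± 14567 to 25753 ± 1655 CPM (-2.02, adjusted p = 0.00931). Me1, which supplies reducing power for this synthesis, fell by 2.57 on the log2 scale (adjusted p = 0.000663). Each of these 5 genes was lower in each HFCD library than in any control library. Of the 22 de novo lipogenesis genes tested, 19 fell and 0 rose (20 and 0 adjusted over the list alone), with a median log2 fold change of -1.74 (camera adjusted p = 2.13e-10). This list had an adjusted p = 0.512 with an estimated correlation. Srebf1, a transcription factor that drives these genes, did not pass (log2 fold change -0.25, SE 0.30, adjusted p = 0.553). Elovl6 (ENSMUSG00000041220) lies on chromosome 3 at 129532355 to 129638495 of GRCm38.

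Mitochondrial genes of adipose tissue were lower under HFCD as well. The mitochondrially encoded genes took up 19.7 ± 8.65% of the counts in control libraries and 4.00 ± 2.06% in HFCD libraries (SD). All 7 of those tested fell (7 adjusted over the list alone; median -2.75, adjusted p = 1.11e-05), among them mt-Cytb of complex III (log2 fold change -3.11, SE 0.59, adjusted p = 0.00333) and mt-Nd4 of complex I (-3.04, adjusted p = 0.00345). Of the 79 oxidative phosphorylation genes encoded in the nucleus, 52 fell and 0 rose (62 and 0 adjusted over the list alone; median -0.74, adjusted p = 7.20e-18). The complex I subunit Ndufb10 fell from 158 ± 32 to 72.3 ± 4.62 CPM (log2 fold change -1.13, SE 0.14, adjusted p = 0.000461), and the complex III subunit Uqcrh fell from 160.4 ± 49.0 to 69.2 ± 7.66 CPM (-1.21, adjusted p = 0.00099). In the tricarboxylic acid cycle list, 17 of 26 genes fell and 2 rose (22 and 2 adjusted over the list alone; median -0.77, adjusted p = 2.64e-08). Pdha1 and Dld are subunits of the complex that feeds pyruvate into that cycle, and they fell by 1.51 and 1.05 on the log2 scale (adjusted p = 0.000564 and 0.00116). For each of these 3 lists, adjusted p = 0.512 with an estimated correlation.

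Genes of the adipocyte itself moved in both directions. Lep, the hormone by which fat tissue reports its stores, rose from 686 ± 291 to 4181 ± 989 CPM (log2 fold change 2.61, SE 0.33, adjusted p = 0.000564). Sfrp5, a secreted inhibitor of Wnt signalling, rose from 26.3 ± 20.2 to 509 ± 85.3 CPM (log2 fold change 4.26, SE 0.72, adjusted p = 0.00207). Pnpla2, the lipase that starts the breakdown of stored fat, fell from 3269 ± 693 to 1449 ± 125 CPM (-1.17, adjusted p = 0.00242), and the adrenergic receptor Adrb3 fell by 2.5 on the log2 scale (adjusted p = 0.00176). The insulin-regulated glucose transporter Slc2a4 fell as well (-0.88, adjusted p = 0.0161), a call that was lost without control replicate 1 (-0.87, adjusted p = 0.0529) or 3 (-0.71, adjusted p = 0.0737). Adipoq, which encodes adiponectin, did not pass (log2 fold change -0.51, SE 0.30, adjusted p = 0.204). Of 28 adipocyte identity genes, 14 fell and 1 rose (16 and 1 adjusted over the list alone; median -0.74, adjusted p = 0.00102), and adjusted p = 0.526 with an estimated correlation. Calls of the thermogenic genes rested on control replicate 1. Without it, Cidea went from -3.79, adjusted p = 0.0191 to -0.72, adjusted p = 0.536, the thyroid-hormone deiodinase Dio2 from -3.74, adjusted p = 0.00774 to -1.60, adjusted p = 0.0925, and the coactivator Ppargc1a from -1.44, adjusted p = 0.036 to -0.30, adjusted p = 0.504. Ppargc1a also lost its call without HFCD replicate 2, 3 or 4 (adjusted p = 0.0894, 0.074 and 0.0649). The uncoupling protein Ucp1 did not pass (log2 fold change -4.15, SE 1.91, adjusted p = 0.117), and its sign turned without control replicate 1 (2.99).

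Immune and dividing-cell genes rose in adipose tissue under HFCD. Itgax, an integrin of tissue macrophages, rose from 4.62 ± 2.51 to 111 ± 11.7 CPM (log2 fold change 4.54, SE 0.71, adjusted p = 0.00154), and the proton pump subunit Atp6v0d2 rose from 4.72 ± 3.98 to 195 ± 73.6 CPM (log2 fold change 5.30, SE 1.15, adjusted p = 0.00603). Of 26 macrophage genes 19 rose and 0 fell (21 and 1 adjusted over the list alone; median 1.73, adjusted p = 3.35e-08), and of 22 lipid-associated macrophage genes 16 rose and 0 fell (16 and 0 adjusted over the list alone; median 2.06, adjusted p = 1.02e-05). The pore-forming protein Mpeg1 rose by 3.47 on the log2 scale (adjusted p = 0.00287), the lipid-sensing receptor Trem2 by 3.05 (adjusted p = 0.0142), the lysosomal glycoprotein Cd68 by 2.93 (adjusted p = 0.0126) and the cytokine Tnf, at 1.67 ± 0.194 CPM in HFCD, by 2.35 (adjusted p = 0.00529). Cd68 and Trem2 lost their calls without control replicate 1 (adjusted p = 0.0515 and 0.0546) or 3 (adjusted p = 0.0504 and 0.0565). The monocyte attractant Ccl2 did not pass (log2 fold change 0.96, SE 0.76, adjusted p = 0.361). Of 38 cell proliferation genes 35 rose and 0 fell (36 and 0 adjusted over the list alone; median 2.00, adjusted p = 2.13e-10), among them the division marker Mki67 (2.56, adjusted p = 0.00205) and the mitotic protein Birc5 (2.72, adjusted p = 0.00268). For these 3 lists adjusted p = 0.512 with an estimated correlation. H2-DMb1, which loads peptides onto class II molecules, rose from 13 ± 3.39 to 66.3 ± 14 CPM (2.34, adjusted p = 0.000402), and 11 of 24 antigen presentation genes rose (15 adjusted over the list alone; median 0.69, adjusted p = 3.33e-05). That list had an adjusted p = 0.512 with an estimated correlation, and a median of 0.41 without HFCD replicate 2.

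Matrix genes rose and mesothelial genes fell in the same comparison. Col6a3, a chain of the collagen that surrounds adipocytes, rose from 176 ± 65.1 to 536 ± 25.3 CPM (log2 fold change 1.60, SE 0.24, adjusted p = 0.00113), and Col8a1 rose from 4.53 ± 0.346 to 15.7 ± 1.46 CPM (1.79, adjusted p = 0.00025). Of 48 extracellular matrix and fibrosis genes, 23 rose and 0 fell (24 and 0 adjusted over the list alone), with a median of 0.91 (adjusted p = 9.38e-08). Its adjusted p = 0.512 with an estimated correlation, and its median was 0.57 without control replicate 1. Wt1, a transcription factor of the mesothelium, the cell layer that covers abdominal fat, fell from 44.5 ± 8.02 to 10.3 ± 4.99 CPM (-2.12, adjusted p = 0.00855). Of 15 mesothelial genes 9 fell and 0 rose (13 and 0 adjusted over the list alone; median -2.06, adjusted p = 0.000208; adjusted p = 0.557 with an estimated correlation). The endothelial apelin receptor Aplnr rose from 12.7 ± 3.80 to 66.8 ± 7.73 CPM (2.41, adjusted p = 0.00128). The largest rises included Slc5a7, a choline transporter at 0.173 ± 0.0669 CPM in control (log2 fold change 9.02, SE 1.15, adjusted p = 0.000564), and Tph2, a tryptophan hydroxylase, from 1.23 ± 0.489 to 64.2 ± 42 CPM (log2 fold change 5.61, SE 0.54, adjusted p = 0.00025). Mup11 had a log2 fold change of -6.93 (adjusted p = 0.0015), which is uncertain because reads are shared within its gene family. The clock gene Nr1d1 fell (-1.60, adjusted p = 0.0194), a call lost without control replicate 1 or 3 or HFCD replicate 2 (highest adjusted p = 0.0607). Dbp (-0.49, adjusted p = 0.42) and Arntl (0.30, adjusted p = 0.499) did not pass. The circadian clock list was lower (median -0.45, adjusted p = 0.0385; adjusted p = 0.512 with an estimated correlation). It was not called without control replicate 1 or 3 or HFCD replicate 4 (highest adjusted p = 0.0796). In all, 2379 genes rose and 2153 fell of 15112 tested, 2160 of them by more than 2-fold, and 24 of 47 lists passed. Without control replicate 1 the count of 4532 genes was 2348, and without control replicate 3 it was 2991.

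**Figure D1:**
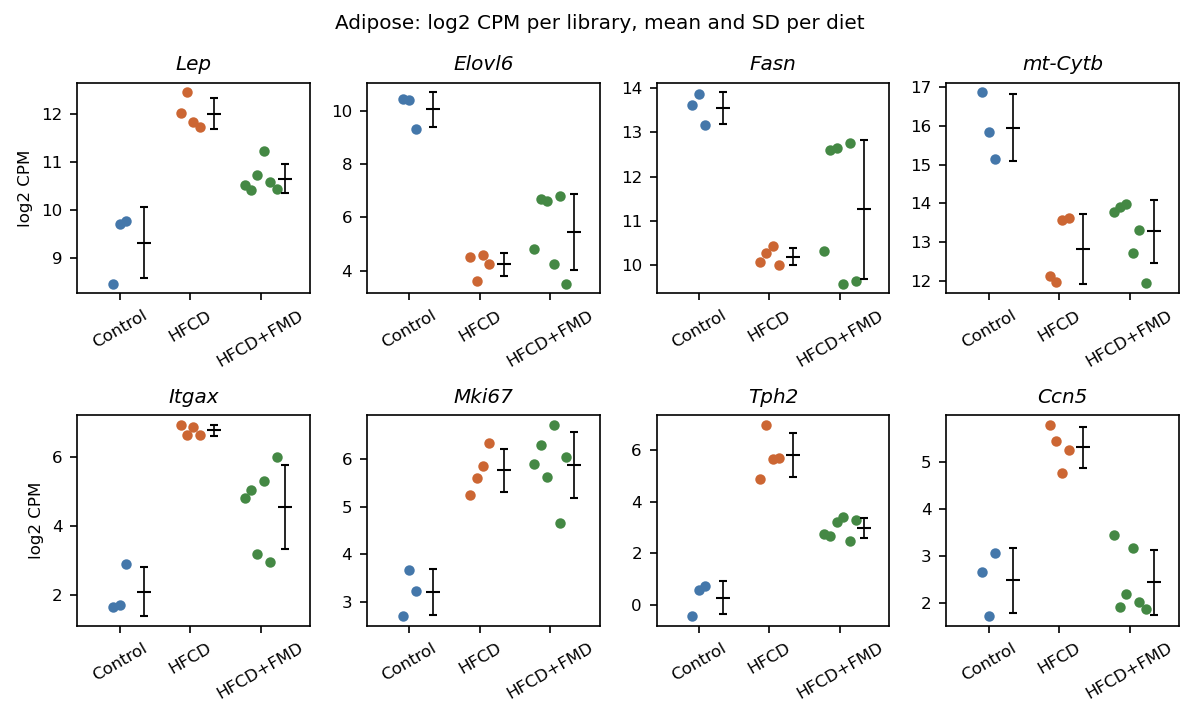
Log2 CPM of 8 genes in adipose tissue, with 1 point per library (3 control, 4 HFCD, 6 HFCD+FMD) and the mean and SD of each diet beside the points. Fasn was 12.60, 12.65 and 12.77 in HFCD+FMD replicates 2, 3 and 5 and 10.32, 9.59 and 9.65 in replicates 1, 4 and 6.

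HFCD+FMD was compared with HFCD in adipose tissue (n = 6 and n = 4) to ask what differed when fasting cycles interrupted HFCD. From cycle 6 the HFCD+FMD mice also ate control diet for 2 days after each fast. Tissue was taken 4 days after the last cycle, so effects of the cycles and of recent feeding cannot be told apart in either tissue. Tph2 was lower in each HFCD+FMD library than in any HFCD library, falling from 64.2 ± 42 to 7.99 ± 2.06 CPM (SD; log2 fold change -3.01, SE 0.34, adjusted p = 0.00679). Ccn5, a secreted protein of connective tissue cells, fell from 40.9 ± 11.7 to 5.96 ± 3.15 CPM (log2 fold change -2.78, SE 0.36, adjusted p = 0.00977), which is at the control mean of 5.95 ± 2.55 CPM. Gas2l2, which links actin to microtubules, fell from 6.61 ± 1.64 to 0.8 ± 0.356 CPM (log2 fold change -3.05, SE 0.38, adjusted p = 0.00913), and the sodium pump subunit Atp1a4 fell from 6.75 ± 1.34 to 1.63 ± 0.428 CPM (log2 fold change -2.05, SE 0.24, adjusted p = 0.00679). Ntm, an adhesion protein, fell from 16.3 ± 3.28 to 3.67 ± 1.70 CPM (-2.16, adjusted p = 0.0133), Cntn2 by 2.39 (adjusted p = 0.0238) and the sodium channel Scn8a by 2.08 (adjusted p = 0.0462) on the log2 scale. The phospholipase Pla2g5 fell by 2.42 (adjusted p = 0.0292), Tcerg1l by 4.46 (adjusted p = 0.0317) and H2-DMb1 by 1.17 (adjusted p = 0.0346). The prolactin receptor Prlr rose from 17.2 ± 4.26 to 42.7 ± 11.9 CPM (log2 fold change 1.31, SE 0.23, adjusted p = 0.0338) and the tubulin Tuba4a from 11.2 ± 1.39 to 24.4 ± 4.94 CPM (log2 fold change 1.12, SE 0.17, adjusted p = 0.0238). Tph2 (ENSMUSG00000006764) lies on chromosome 10 at 115078641 to 115185022 of GRCm38.

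In this comparison 4 genes rose and 27 fell, 25 of them by more than 2-fold (1693 genes had an unadjusted p below 0.05, with 756 expected by chance). DESeq2 called 302 genes, voom 60 and voom with quality weights 472. Without 1 library the count was 9, 11, 80 and 8 (HFCD+FMD replicates 2, 3, 4 and 5) or 10, 10, 9 and 5 (HFCD replicates 1, 2, 3 and 4). Tph2, Gas2l2, Ccn5 and Atp1a4 passed in each of the 13 fits without 1 library, and Ntm in each but that without HFCD replicate 4 (-2.08, adjusted p = 0.0698). Cntn2, Scn8a, Pla2g5, Tcerg1l, H2-DMb1, Prlr and Tuba4a lost their calls without HFCD+FMD replicate 3 or 5 or HFCD replicate 4, and in 5 to 10 of those 13 fits, with a highest adjusted p between 0.0879 (Cntn2) and 0.204 (Scn8a). Lep did not pass (1634 ± 386 against 4181 ± 989 CPM; log2 fold change -1.36, SE 0.25, adjusted p = 0.0553), nor did Fasn (log2 fold change 1.66, SE 0.64, adjusted p = 0.36), Itgax (log2 fold change -1.86, SE 0.48, adjusted p = 0.174), Slc2a4 (0.57, adjusted p = 0.333), Trem2 (-0.97, adjusted p = 0.556) or Cd68 (-0.82, adjusted p = 0.606). The other genes reported whatever their result also did not pass, with log2 fold changes of 0.26 for Pnpla2, 0.13 for Adipoq, -0.39 for Ucp1, 0.54 for Cidea, 0.33 for Ppargc1a, -0.14 for Scd1, 0.34 for Srebf1, 0.44 for Ccl2, 0.10 for Tnf, -0.32 for Col6a3, 0.50 for Dbp and -0.20 for Arntl.

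Groups of genes shifted together where few single genes passed, and 17 of 47 lists were called. None of the 79 oxidative phosphorylation genes passed over all genes tested, 12 were higher and 0 lower when adjusted over the list alone, and the list's median was 0.33 (adjusted p = 6.73e-18). For the tricarboxylic acid cycle 8 were higher and 1 lower adjusted over the list alone (median 0.36, adjusted p = 2.44e-08), and for de novo lipogenesis 4 and 0 (median 0.62, adjusted p = 4.75e-06). The B and plasma cell list was higher (median 0.97, adjusted p = 3.67e-05), with 0 genes adjusted over the list alone and a median of 1.59 without HFCD replicate 4. For these 4 lists adjusted p = 0.548 with an estimated correlation. Lipid-associated macrophage genes were lower (median -0.54, adjusted p = 9.74e-06; -0.35 without HFCD+FMD replicate 3), with 1 gene adjusted over the list alone and an adjusted p = 0.602 with an estimated correlation. The macrophage list (median -0.48, adjusted p = 0.00303), the extracellular matrix list (median -0.17, adjusted p = 0.00587) and the mesothelial list (median 0.94, adjusted p = 0.00574) had adjusted p = 0.779 with an estimated correlation. They were not called without HFCD replicate 4 (-0.26, adjusted p = 0.0795; -0.06, adjusted p = 0.0757; 0.66, adjusted p = 0.119), and the matrix list had a median of -0.39 without HFCD+FMD replicate 4. Adjusted over the list alone, 0 macrophage, 1 matrix and 0 mesothelial genes passed.

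HFCD+FMD was also set against control in adipose tissue (n = 6 and n = 3) to ask which differences from the control diet were present with the cycles. Elovl6 fell from 1125 ± 429 CPM in control to 61.5 ± 46.5 CPM (SD; log2 fold change -4.19, SE 0.62, adjusted p = 0.00236), Scd1 by 2.16 (adjusted p = 0.00753) and Me1 by 2.12 on the log2 scale (adjusted p = 0.00201). Mki67 rose from 9.43 ± 3.10 to 64.2 ± 27.3 CPM (log2 fold change 2.75, SE 0.42, adjusted p = 0.00262), and so did the topoisomerase Top2a (2.56, adjusted p = 0.00306). Col6a3 rose to 429 ± 77.7 CPM (log2 fold change 1.28, SE 0.22, adjusted p = 0.00422), Col8a1 by 1.39 (adjusted p = 0.0011), Aplnr by 2.79 (adjusted p = 0.00183), Slc5a7 by 7.65 (adjusted p = 0.00233) and Tnf by 2.44 (adjusted p = 0.00694). mt-Cytb fell from 71541 ± 43244 to 11081 ± 4987 CPM (log2 fold change -2.69, SE 0.51, adjusted p = 0.00603) and Pdha1 by 0.98 (adjusted p = 0.00442). The largest falls were in Pdzk1ip1 (-4.53, adjusted p = 0.00128), the airway-type oxidase Cyp2f2 (-4.40, adjusted p = 0.0036) and Mup3 (-4.25, adjusted p = 0.00258), the last uncertain because its family shares reads. Lep rose to 1634 ± 386 CPM (log2 fold change 1.25, SE 0.30, adjusted p = 0.0154), a call lost without control replicate 1 (0.94, adjusted p = 0.0624). Cd68 was higher (2.11, adjusted p = 0.0488), a call lost in 8 of the 13 fits without 1 library (highest adjusted p = 0.178). Itgax was higher (2.68, adjusted p = 0.0153), but not called without control replicate 1 or 3 (adjusted p = 0.08 and 0.0666). Pnpla2 (-0.92, adjusted p = 0.00843), Cidea (-3.25, adjusted p = 0.0268) and Dio2 (-3.57, adjusted p = 0.00869) fell, and each lost its call without control replicate 1 (-0.76, adjusted p = 0.0537; -0.18, adjusted p = 0.902; -1.44, adjusted p = 0.14). Fasn (-1.71, adjusted p = 0.0716), Trem2 (2.08, adjusted p = 0.0638), Ucp1 (-4.54, adjusted p = 0.0702), Ppargc1a (-1.10, adjusted p = 0.0816), Ccl2 (1.40, adjusted p = 0.189), Adipoq (-0.38, adjusted p = 0.328), Slc2a4 (-0.31, adjusted p = 0.329), Srebf1 (0.09, adjusted p = 0.839), Dbp (0.01, adjusted p = 0.986) and Arntl (0.09, adjusted p = 0.847) did not pass.

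In this comparison 1580 genes rose and 1398 fell, 1312 of them by more than 2-fold, and 17 of 47 lists were called. Without control replicate 1 the count of 2978 was 663, and without control replicate 3 it was 1164. Of 38 cell proliferation genes 35 rose and 0 fell (37 and 0 adjusted over the list alone; median 2.13, adjusted p = 3.07e-14), and of 48 matrix genes 16 rose (23 adjusted over the list alone; median 0.62, adjusted p = 2.45e-07). Both had an adjusted p = 0.622 with an estimated correlation, and the matrix median was 0.37 and 1.01 without control replicates 1 and 5. Of 26 macrophage genes 12 rose (15 adjusted over the list alone; median 1.27, adjusted p = 1.31e-07; adjusted p = 0.622 with an estimated correlation), with a median of 2.02 without control replicate 5. Interferon response genes were higher (median 0.89, adjusted p = 2.38e-06), and 7 of 41 rose (7 adjusted over the list alone). Of 79 oxidative phosphorylation genes 24 fell and 0 rose (28 and 0 adjusted over the list alone; median -0.38, adjusted p = 2.61e-09; -0.12 without control replicate 1). These 2 lists had an adjusted p = 0.659 with an estimated correlation. De novo lipogenesis genes fell in 12 of 22 cases (17 adjusted over the list alone; median -1.33, adjusted p = 3.15e-08), and 11 of 22 endothelial genes rose (14 adjusted over the list alone; median 0.58, adjusted p = 1.75e-06). Both had an adjusted p = 0.596 with an estimated correlation.

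**Figure D2:**
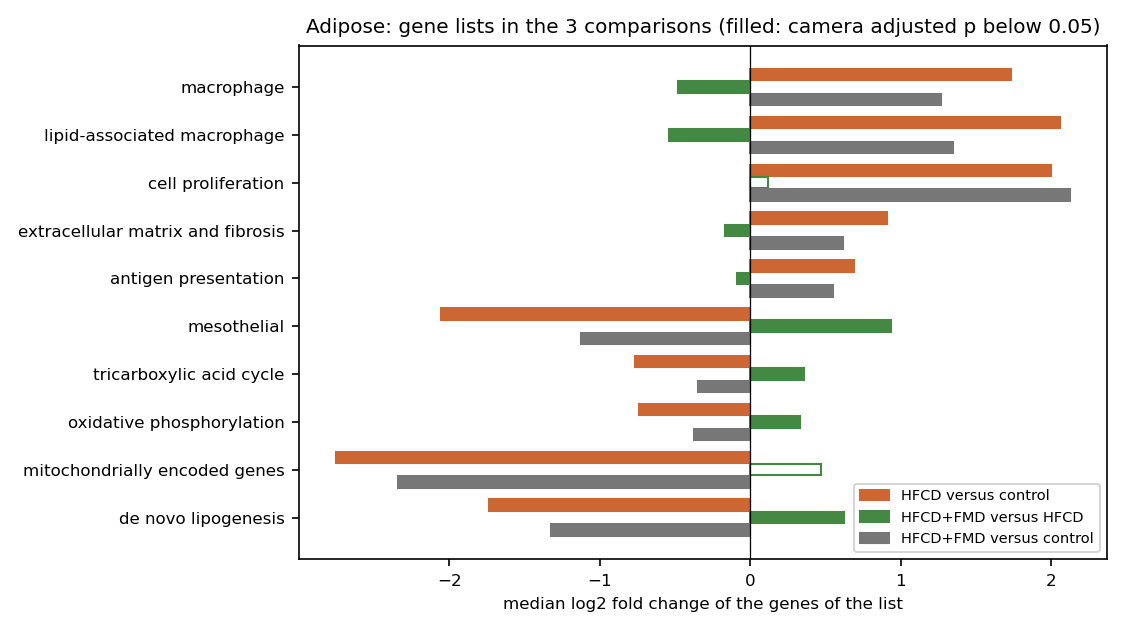
Median log2 fold change of the genes of 10 lists in adipose tissue (horizontal axis), with 1 bar for each of 3 comparisons and filled bars where the camera adjusted p passed. The macrophage list was at 1.73, -0.48 and 1.27 in HFCD versus control, HFCD+FMD versus HFCD and HFCD+FMD versus control, and cell proliferation at 2.00, 0.12 and 2.13.

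Whether the cycles moved adipose genes back toward control was read from the signs of the fold changes. Of the 4532 genes changed by HFCD, 3927 (86.7%, 95% interval 85.6% to 87.6%) had the opposite sign in HFCD+FMD versus HFCD. Part of such a share arises because both comparisons contain the HFCD libraries: it averaged 61.4% in simulated data without any effect of the cycles (59.7% to 62.8% over 20 draws). With the HFCD libraries divided so that none was shared it averaged 79.0% over 6 divisions (63.2% to 88.0%). Among the 31 genes that passed for the cycles, 25 had risen under HFCD and fell with the cycles, among them Tph2, Ccn5, Gas2l2 and Ntm. Another 4 had fallen under HFCD and rose with the cycles, 2 passed in HFCD+FMD versus HFCD alone, and 0 moved further the same way. Independent lists of these sizes would share 4.25 and 0.57 such genes, values that leave out the shared HFCD libraries. The simulated data called 0.35 genes for the cycles on average. The 31 genes of smallest p in each draw held 7.6 that rose and then fell (4 to 12) and 6.2 that fell and then rose (3 to 10).

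In heart, the comparison of HFCD with control (n = 5 and n = 5) asked what the diet changed in the aged heart. No single gene passed. Mthfd2, a mitochondrial enzyme of folate metabolism, stood at 7.40 ± 5.33 CPM in HFCD and 2.23 ± 0.557 CPM in control (SD; log2 fold change 1.56, SE 0.26, adjusted p = 0.132), and the folate enzyme Aldh1l2 at 14 ± 5.48 and 7.13 ± 2.74 CPM (log2 fold change 1.06, SE 0.19, adjusted p = 0.132). The glutamate transporter Slc1a2 (1.82, adjusted p = 0.132), the centrosomal protein Tacc2 (1.05, adjusted p = 0.132) and the neuropeptide precursor Tac1 (-0.93, adjusted p = 0.132) did not pass either. Pdk4, which keeps pyruvate out of the mitochondrion, was at 1409 ± 1340.4 and 598 ± 325 CPM (log2 fold change 1.31, SE 0.39, adjusted p = 0.367). The natriuretic peptides Nppa (log2 fold change 1.99, SE 1.27, adjusted p = 0.476) and Nppb (-0.72, adjusted p = 0.47) did not pass, nor did Ucp3 (0.66, adjusted p = 0.376), Cpt1b (0.48, adjusted p = 0.385), Angptl4 (0.60, adjusted p = 0.539), Myh7 (-0.01, adjusted p = 0.997), Col1a1 (0.06, adjusted p = 0.912), Col3a1 (-0.04, adjusted p = 0.921), Ccn2 (0.16, adjusted p = 0.837), Dbp (-0.11, adjusted p = 0.829) and Arntl (-0.90, adjusted p = 0.385). The edgeR count was 0 of 13230 genes (1687 at an unadjusted p below 0.05, with 662 expected), against 61 with DESeq2, 0 with voom, 226 with voom and quality weights and 51 on the deposited log2 values. Set A, 3 control and 4 HFCD libraries, gave 0 genes on its own (1641 at an unadjusted p below 0.05), and sets B and C hold too few libraries of both diets.

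In heart under HFCD 12 of 44 lists were called. PPAR target genes, which answer to fatty acids, were higher (median 0.40, adjusted p = 3.89e-06, 0.31 in set A), 7 up and 1 down adjusted over the list alone. The 7 mitochondrially encoded genes were higher (median 1.18, adjusted p = 0.000847; 1.32 in set A; 0.53 without HFCD replicate 3), 3 of them adjusted over the list alone. Oxidative phosphorylation genes were lower (median -0.52, adjusted p = 5.45e-19; -0.63 in set A), and so were cytosolic ribosomal protein genes (median -0.50, adjusted p = 3.04e-07; -0.65 in set A), with 0 and 3 genes passing adjusted over the list alone. Without control replicate 2 those medians were -0.18 and -0.19. Glycolysis and glucose uptake genes were lower (median -0.27, adjusted p = 0.000291; -0.24 in set A; -0.17 without control replicate 2), 2 of 23 adjusted over the list alone. Immediate early genes were lower (median -0.57, adjusted p = 0.000133; -0.50 in set A), none adjusted over the list alone, with medians of -0.29, -0.88 and -1.03 without control replicates 3 and 5 and HFCD replicate 4 and -0.29 without the set factor. For these 6 lists adjusted p = 0.728 with an estimated correlation. Fatty acid oxidation genes were higher (median 0.27, adjusted p = 0.00381; adjusted p = 0.879 with an estimated correlation; 3 adjusted over the list alone), but not without control replicate 5 (adjusted p = 0.0553), HFCD replicate 4 (adjusted p = 0.0873) or the set factor (0.16, adjusted p = 0.302). Atrial tissue genes were higher (median 1.13, adjusted p = 0.0122; adjusted p = 0.949 with an estimated correlation), and contractile and calcium handling genes of cardiomyocytes were lower (median -0.26, adjusted p = 0.000794; adjusted p = 0.728 with an estimated correlation). In each of these lists 0 genes passed adjusted over the list alone with edgeR. The atrial list was not called without HFCD replicate 3 (0.22, adjusted p = 0.117), HFCD replicate 5 (0.73, adjusted p = 0.359) or HFCD+FMD replicate 1 (0.93, adjusted p = 0.433), nor in set A (0.73, adjusted p = 0.269). Without a set factor and HFCD replicates 3 and 5 its median was -0.31. The contractile list was not called without HFCD replicate 5 (adjusted p = 0.0818) or HFCD+FMD replicate 1 (adjusted p = 0.0874), nor in set A (adjusted p = 0.116). Its median was -0.13 without control replicate 2. The share of counts from mitochondrially encoded genes was 27.2 ± 4.06% in control, 49.6 ± 15.4% in HFCD and 45.8 ± 18.4% in HFCD+FMD libraries (SD).

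HFCD+FMD was compared with HFCD in heart (n = 4 and n = 5) to ask what the cycles changed there. All 14 genes that passed fell, and 0 rose (1454 had an unadjusted p below 0.05, with 662 expected). Bmp10, a growth factor of atrial muscle, stood at 0.855 ± 1.17 CPM in HFCD+FMD and 171 ± 380.0 CPM in HFCD (SD; log2 fold change -9.25, SE 0.98, adjusted p = 0.00295). Fat and plasma protein genes were among them: the haemoglobin binder Hp (0.0804 ± 0.0904 against 5.83 ± 12.5 CPM; -7.56, adjusted p = 0.0113), the lipid droplet protein Cidec (0.0396 ± 0.0503 against 1.84 ± 3.53 CPM; -6.92, adjusted p = 0.0392) and the adipsin gene Cfd (0.228 ± 0.106 against 5.78 ± 12.4 CPM; -6.24, adjusted p = 0.0392). Pdk4 fell from 1409 ± 1340.4 to 404 ± 61.4 CPM (log2 fold change -2.77, SE 0.47, adjusted p = 0.0405). The haem oxygenase Hmox1 (-2.88, adjusted p = 0.0392), the metallothionein Mt2 (-3.79, adjusted p = 0.0392), the transcription factor Myc (-2.33, adjusted p = 0.0392), Trim67 (-3.27, adjusted p = 0.0392) and the macrophage receptor Vsig4 (-2.70, adjusted p = 0.0454) also fell. HFCD replicate 5, the only HFCD library of set C, carried a weight of 0.61 of 1 for HFCD in this model. Without it the weight of HFCD+FMD lay on replicate 1 alone, so the count of 0 genes in that fit does not show whether the calls hold. In a model without the set factor 0 genes passed, and the values were Bmp10 -7.58 (adjusted p = 0.366), Hp -5.76 (adjusted p = 0.35), Cidec -5.11 (adjusted p = 0.343), Cfd -4.78 (adjusted p = 0.395), Mt2 -2.88 (adjusted p = 0.343), Trim67 -2.38 (adjusted p = 0.27), Hmox1 -2.14 (adjusted p = 0.399), Pdk4 -1.80 (adjusted p = 0.353), Vsig4 -1.59 (adjusted p = 0.507) and Myc -1.53 (adjusted p = 0.424). With HFCD replicate 5 left out of that model 77 genes passed, 0 of them among the 14. The log2 fold change was then 0.43 for Bmp10, -0.23 for Cfd, -0.25 for Vsig4, -0.40 for Myc, -0.41 for Hmox1, -1.06 for Trim67, -1.07 for Pdk4, -1.31 for Mt2 and -2.11 for Cidec, with Hp removed by the low-count filter. With replicate 3 left out too 203 passed, again 0 of the 14. The count without 1 other library was 79, 2, 37 and 3 (control replicates 2, 3, 4 and 6), 368, 1, 0 and 1 (HFCD+FMD replicates 1, 2, 3 and 5) or 2, 22 and 2 (HFCD replicates 2, 3 and 4). In the fit without HFCD+FMD replicate 1, HFCD replicate 5 alone stood for HFCD. Bmp10 also lost its call without HFCD+FMD replicate 3 (adjusted p = 0.0577), Hp without HFCD+FMD replicates 2, 3 and 5 (adjusted p = 0.0901, 0.102 and 0.127), and the 8 other named genes in 7 to 9 of the 14 fits without 1 library. DESeq2 called 279 genes, voom 16 and voom with quality weights 13.

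Of the heart genes reported whatever their result, Angptl4 (log2 fold change -3.07, SE 0.58, adjusted p = 0.0584), Ucp3 (log2 fold change -1.76, SE 0.33, adjusted p = 0.0584) and Ccn2 (log2 fold change -2.11, SE 0.43, adjusted p = 0.0711) came closest to passing in HFCD+FMD versus HFCD. Nppa (-4.70, adjusted p = 0.308), Cpt1b (-0.10, adjusted p = 0.955), Nppb (0.34, adjusted p = 0.911), Myh7 (0.19, adjusted p = 0.972), Col1a1 (0.09, adjusted p = 0.961), Col3a1 (0.37, adjusted p = 0.604), Dbp (0.99, adjusted p = 0.239) and Arntl (-1.24, adjusted p = 0.342) did not pass. Of 44 lists, 24 were called. Atrial tissue genes were lower (median -2.03, adjusted p = 7.78e-15), with 1 of 15 passing over all genes tested and 12 adjusted over the list alone. Complement genes were lower (median -0.76, adjusted p = 1.51e-08; 1 over all genes and 10 adjusted over the list alone), and so were adipocyte identity genes (median -0.69, adjusted p = 7.08e-08; 2 and 9 adjusted over the list alone). For these 3 lists adjusted p = 0.185 with an estimated correlation, and none was called without HFCD replicate 5, where HFCD+FMD replicate 1 stood alone (-0.48, adjusted p = 0.236; -0.24, adjusted p = 0.424; 0.01, adjusted p = 0.687). Nor was any called with the set factor dropped as well (-0.41, adjusted p = 0.0846; 0.01, adjusted p = 0.774; -0.23, adjusted p = 0.0674). With replicate 3 left out too, adipocyte identity was called (-0.33, adjusted p = 0.0119). Without the set factor alone the complement list was not called (-0.36, adjusted p = 0.125). The atrial median was -3.21 without HFCD+FMD replicate 1. PPAR target genes were lower (median -0.37, adjusted p = 1.32e-07; adjusted p = 0.248 with an estimated correlation), 1 over all genes and 12 adjusted over the list alone. They were still called without HFCD replicate 5 and the set factor (-0.18, adjusted p = 0.0115), and the median was -0.59 and -0.24 without HFCD+FMD replicates 2 and 5 and -0.18 without HFCD replicate 5. Oxidative phosphorylation genes were higher (median 0.34, adjusted p = 6.37e-08; adjusted p = 0.481 with an estimated correlation), none adjusted over the list alone, with medians of 0.64 without HFCD replicate 5, 0.15 without HFCD+FMD replicate 1, 0.18 without control replicate 2 and 0.25 without HFCD replicate 5 and the set factor. No set held at least 2 libraries of both diets.

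**Figure D3:**
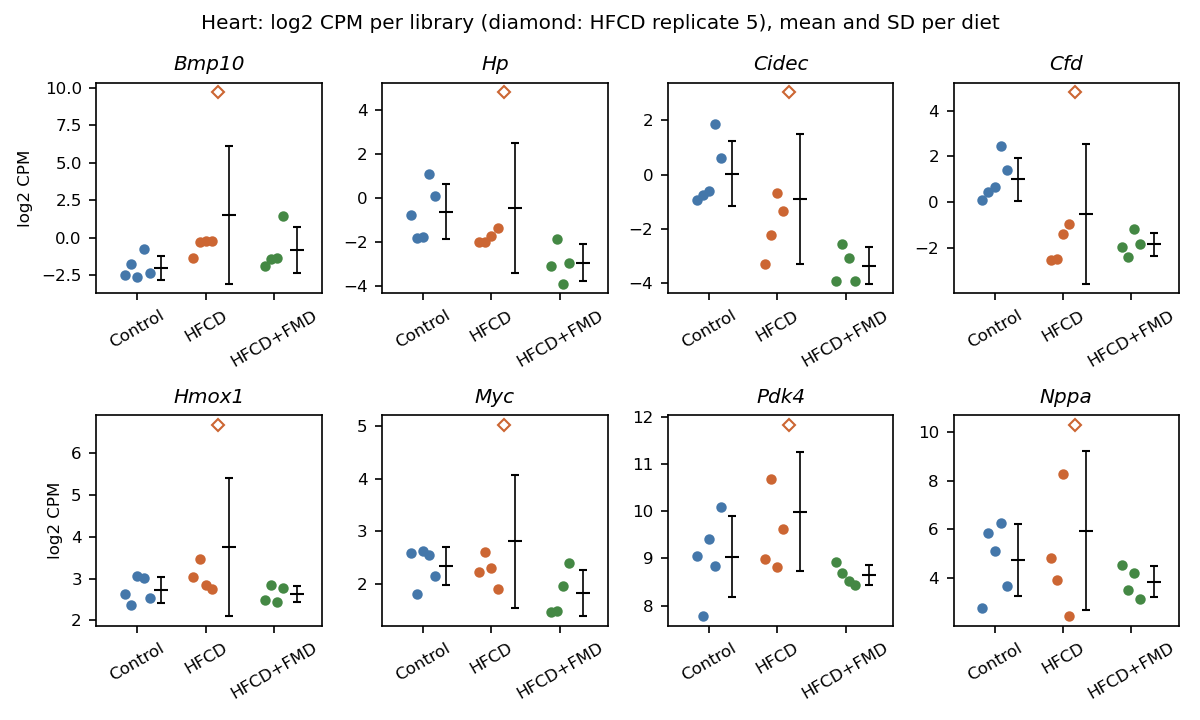
Log2 CPM of 8 genes in heart, with 1 point per library (5 control, 5 HFCD, 4 HFCD+FMD) and the mean and SD of each diet beside the points. The open diamond is HFCD replicate 5, which stood at 9.73 for Bmp10 and 4.82 for Hp.

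HFCD+FMD was set against control in heart (n = 4 and n = 5) to ask which genes differed from the control diet after the cycles. Cidec, Hp and Cfd fell and 0 genes rose (1254 had an unadjusted p below 0.05, with 662 expected; DESeq2 called 145 genes, voom 1 and voom with quality weights 26). Cfd stood at 0.228 ± 0.106 CPM in HFCD+FMD and 2.36 ± 1.79 CPM in control (SD; log2 fold change -9.13, SE 1.19, adjusted p = 0.0155), Cidec at 0.0396 ± 0.0503 and 1.33 ± 1.33 CPM (log2 fold change -9.58, SE 1.29, adjusted p = 0.0157) and Hp at 0.0804 ± 0.0904 and 0.817 ± 0.785 CPM (log2 fold change -9.40, SE 1.18, adjusted p = 0.0155). Without the set factor 0 genes passed, with Cidec at -4.62, adjusted p = 0.142, Hp at -2.93, adjusted p = 0.341 and Cfd at -3.48, adjusted p = 0.233. With HFCD replicate 5 left out of that model 184 passed, among them Cidec (-4.60, adjusted p = 0.0252) and Cfd (-3.48, adjusted p = 0.00986). With replicate 3 left out too 774 passed, Hp among them (-2.93, adjusted p = 0.0444). With the set factor the count was 0 without HFCD+FMD replicate 2, 3 or 5 or HFCD replicate 2 or 5, 217 without HFCD+FMD replicate 1, and 8 without control replicate 2 or HFCD replicate 3. Without HFCD replicate 5 that model set HFCD+FMD replicate 1 alone against control replicates 4 and 6. Adipoq (log2 fold change -7.81, SE 1.20, adjusted p = 0.0506) and the carbonic anhydrase relative Car8 (29.8 ± 2.19 against 18.5 ± 2.93 CPM; log2 fold change 1.13, SE 0.18, adjusted p = 0.0711) came next and did not pass. Nor did Angptl4 (-2.46, adjusted p = 0.174), Pdk4 (-1.46, adjusted p = 0.345), Ucp3 (-1.09, adjusted p = 0.313), Arntl (-2.14, adjusted p = 0.174), Nppa (-2.71, adjusted p = 0.633), Cpt1b (0.38, adjusted p = 0.691), Nppb (-0.38, adjusted p = 0.856), Myh7 (0.18, adjusted p = 0.963), Col1a1 (0.16, adjusted p = 0.885), Col3a1 (0.33, adjusted p = 0.668), Ccn2 (-1.95, adjusted p = 0.162) or Dbp (0.88, adjusted p = 0.396). Of 44 lists 21 were called. Glucocorticoid response genes were lower (median -0.75, adjusted p = 4.89e-07), with 11 of 24 adjusted over the list alone, and so were immediate early genes (median -0.78, adjusted p = 4.89e-07; 3 adjusted over the list alone). The immediate early median was -0.36 without HFCD+FMD replicate 1, -0.49 without control replicate 6 and -0.37 without the set factor. Cell proliferation genes were higher (median 0.77, adjusted p = 4.89e-07; 1 gene adjusted over the list alone), with 0.15, adjusted p = 0.368 without HFCD replicate 5 and 1.38 without HFCD+FMD replicate 1. Without the set factor the median was 0.51, and with HFCD replicate 5 left out as well the list was still called (0.51, adjusted p = 2.91e-05). For these 3 lists adjusted p = 0.282 with an estimated correlation. Sets B and C hold too few libraries of both diets for a comparison within them.

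Across all 13230 heart genes, used because fewer than 10 passed for HFCD versus control, 8441 (63.8%, 95% interval 63.0% to 64.6%) had opposite signs in HFCD versus control and in HFCD+FMD versus HFCD. Simulated data without any effect of the cycles gave 56.4% (55.7% to 57.3%), and HFCD libraries divided so that none was shared gave a mean of 56.7% over 20 divisions (40.8% to 64.4%). Without HFCD+FMD replicate 1, where HFCD replicate 5 alone stood for HFCD, the share was 44.7%, below the simulated value. Among the 347 genes with an unadjusted p below 0.01 for HFCD versus control it was 90.5%. Genes selected in that way in the simulated data gave 66.5% (64.0% to 68.5%).

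Responses to the diets were compared between the 2 tissues, treated as independent although some mice gave both. Chance is not excluded for the differences, as the shuffles below show. For HFCD versus control, 2778 of 12606 genes expressed in both tissues differed in response, 1440 of them higher in adipose tissue and 1338 lower. Elovl6 responded more negatively in adipose tissue (difference in log2 fold change -5.13, adjusted p = 0.000175), as did mt-Cytb (-4.75, adjusted p = 0.000626), mt-Nd4 (-4.47, adjusted p = 0.000839), Me1 (-2.75, adjusted p = 2.13e-05) and Pdha1 (-1.42, adjusted p = 0.000165). Itgax (4.05, adjusted p = 0.000958), Mpeg1 (3.33, adjusted p = 0.000954), H2-DMb1 (3.01, adjusted p = 0.000122) and Col6a3 (1.60, adjusted p = 0.00046) responded more positively. By list, the median of the differences per gene was -1.74 for de novo lipogenesis (adjusted p = 3.66e-10; adjusted p = 0.577 with an estimated correlation) and 1.71 for macrophage genes (adjusted p = 5.54e-07; adjusted p = 0.717 with an estimated correlation). For HFCD+FMD versus HFCD only Ntm (-2.25, adjusted p = 0.0360) and the muscle lamin-interacting gene Mlip (-2.90, adjusted p = 0.0332) passed. They are named after their values were seen, as no more than 2 passed. Lists that differed numbered 17, 5 and 11 of 45 in HFCD versus control, HFCD+FMD versus HFCD and HFCD+FMD versus control, and 0 with an estimated correlation. Of the 5 called in HFCD+FMD versus HFCD the largest median difference was -0.84 for cardiomyocyte contractile genes. Its adjusted p was 4.82e-12, and 0.511 with an estimated correlation. The median was 0.77 for de novo lipogenesis (adjusted p = 4.94e-05) and 0.46 for the interferon response (adjusted p = 2.61e-06). Both had adjusted p = 0.872 with an estimated correlation. For HFCD+FMD versus control 2152 genes differed, 1099 higher and 1053 lower in adipose tissue. Elovl6 (-4.02, adjusted p = 0.00186) and mt-Cytb (-4.10, adjusted p = 0.00262) were again among the lower ones, and Aplnr (1.89, adjusted p = 0.0229), Col6a3 (0.95, adjusted p = 0.0207) and Psmb8 (1.39, adjusted p = 0.0103), an immunoproteasome subunit, among the higher ones.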

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

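The tests that left out HFCD replicate 5 of heart, the reading of Xist in it, the test of the adipocyte share and the splits within library sets were chosen after the result was seen.

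Oxidative phosphorylation genes of adipose tissue were lower in HFCD than in control (median -0.74, SE between libraries 0.243) and higher in HFCD+FMD than in HFCD (0.33, SE 0.120). A bias by transcript length can differ with RNA quality, and a leftover ribosomal RNA transcript, Gm15564, split the libraries. Each explanation would have the median of HFCD versus control shrink once corrected for. Freed of the length trend it went from -0.74 to -0.50 (camera adjusted p = 6.82e-12), so a length bias may account for part of it. What remained was larger than the SE before that correction, and the SE after it was not computed. With the Gm15564 level as a covariate the median was -0.88, so it did not shrink. For HFCD+FMD versus HFCD the medians were 0.27 and 0.38, but these corrections moved all genes by a median of only 0.0135 and 0.0248, so neither explanation can be excluded there. A lower share of adipocytes stays open: their score was 9.35 to 9.64 in HFCD and 9.67 to 10.49 in control libraries. Not all other cells rose: 4 of 4 HFCD libraries had a macrophage score above and a mesothelial score below all controls. A change in macrophage number, which may dilute adipocyte transcripts, and a response of adipocytes to the diets cannot be separated in whole tissue.

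Heart genes lower in HFCD+FMD than in HFCD may come from 1 HFCD library, replicate 5, that held atrial and fat tissue. In a model without a set factor the 14 genes had a median log2 fold change of -1.97, and without that library it was -0.585. The atrial tissue list went from a median of -1.55 (adjusted p = 0.00114) to -0.408 (adjusted p = 0.0846; SE between libraries 0.795), so the call ended because the fold shrank. HFCD replicate 5 had an atrial score of 7.20, HFCD replicate 3 one of 5.67, and the 12 other heart libraries 2.34 to 4.02, and a change of atrial genes with the diets was not tested apart from how the tissue was cut. The same library may come from a male mouse or carry a wrong label, as Xist was at -0.74 log2 CPM in it and at 5.87 to 7.54 in the 13 others; the labels do not give the sex, and genes of the Y chromosome were not analysed here.

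Oxidative phosphorylation and cytosolic ribosomal protein genes were lower in heart in HFCD than in control (medians -0.52 and -0.50, SE between libraries 0.195 and 0.193). The large share of mitochondrially encoded counts stays open, because leaving those genes out moved all genes by a median of only 0.00707, and the medians of -0.531 and -0.511 without them decide nothing. Within set A alone the medians were -0.63 and -0.65 (SE 0.331 and 0.289). Set A holds control replicate 2, without which the medians over all sets were -0.18 and -0.19, so set A cannot exclude the library sets. A length bias remains possible: both lists hold short transcripts (median 892 and 987 bases against 3160 for all genes), and freed of the length trend the medians were -0.195 (adjusted p = 1.11e-07) and -0.194 (adjusted p = 0.0130), about as large as the SE between libraries. A length effect and an effect of the diet cannot be told apart here, and control replicate 2 had the steepest length trend (3.24 on the log2 scale against 0.07 to 1.75 in the other libraries).

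Other divisions of the same libraries into groups of the same sizes were fitted in the same way. Chance is unlikely for the adipose genes of HFCD versus control (4532, highest other 1, 1 of 35 splits reached it). The same holds for HFCD+FMD versus control (2978, 608, 1 of 84). For HFCD+FMD versus HFCD (31, 3 of 100) it is not excluded, as 1 split called 1048. In heart, splits that ignored the library sets reached the real count in 3 of 99 for the genes of HFCD+FMD versus HFCD (14, highest other 2385) and in 2 of 100 for HFCD+FMD versus control (3, highest other 1914). Diet and library set overlap, however, and splits that keep the diets of each set numbered only 4 (highest other 0, 1 of 4 reached the count) and 3 (highest other 1, 1 of 3), too few for a share under 0.05. Both counts were 0 without the set factor, but 77 and 184 with HFCD replicate 5 left out of that model as well. Splits that called many times the real number point to a structure among the samples. That of 2385 set HFCD+FMD replicates 3 and 5 and HFCD replicates 3 and 5 against the others. Mitochondrially encoded genes took 59.8% to 71.5% of the counts in these and 21.8% to 42.7% in all other heart libraries. That of 1914 set library set B and control replicate 2 against the others, and that of 1048 set HFCD+FMD replicates 1 to 4 and HFCD replicates 3 and 4 of adipose tissue against the others. For the heart genes of HFCD versus control the real count was 0 (highest other 38), which 100 of 100 splits reach whatever the data, so the splits decide nothing. Chance cannot be excluded for the number of gene lists in any comparison. For heart these were 12 (highest other 23, 57 of 100), 24 (28, 9 of 99) and 21 (24, 6 of 100) in HFCD versus control, HFCD+FMD versus HFCD and HFCD+FMD versus control. For adipose tissue they were 24 (32, 11 of 35), 17 (25, 41 of 100) and 17 (30, 43 of 84). Diets shuffled within tissues, ignoring library sets, carry no diet effect and cannot exclude chance for a tissue difference. Counts were reached in 1 of 50 for HFCD versus control (2778, highest other 2743) and 1 of 50 for HFCD+FMD versus control (2152, 397). For HFCD+FMD versus HFCD it was 15 of 50 (2, 749).

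Of 243 checks of a library against the others of its diet, 19 found it far away, where chance finds about 1 in 20. HFCD replicate 5 of heart stood far above the other HFCD libraries, in log2 CPM, for Bmp10 at 9.73 (others -1.35 to -0.22), Hmox1 at 6.69 (2.75 to 3.48), Myc at 5.03 (1.89 to 2.61), Hp at 4.82 (-2.01 to -1.34), Cfd at 4.81 (-2.51 to -0.95), Arntl at 4.11 (1.19 to 1.88), Trim67 at 3.64 (0.29 to 1.14) and Adipoq at 3.23 (-2.84 to -1.13). HFCD+FMD replicate 1 of heart had 13183 genes with a count (others 13227 to 13236) and Tac1 at 1.46 (1.99 to 2.03). Also in heart, HFCD+FMD replicate 3 had Adipoq at -1.37 (-2.69 to -2.60), HFCD+FMD replicate 5 Bmp10 at 1.42 (-1.93 to -1.37), control replicate 2 Cpt1b at 2.84 (3.52 to 3.69) and control replicate 6 Nppb at 4.07 (6.55 to 6.90). In adipose tissue, HFCD replicate 2 had Atp1a4 at 3.14 (2.60 to 2.65), HFCD replicate 3 Ntm at 3.53 (4.12 to 4.24), HFCD replicate 4 Spp1 at 5.16 (4.04 to 4.10), HFCD+FMD replicate 3 Cd247 at 3.83 (3.04 to 3.32) and HFCD+FMD replicate 4 Lep at 11.22 (10.41 to 10.71).

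Genes and lists that the text gives for both tissues under the same comparison had their effects compared between the tissues, and 4 of these 15 effects, all of lists, differed. For HFCD versus control, the median over genes of the adipose minus heart difference was -0.12 for oxidative phosphorylation (adjusted p = 0.0427; adjusted p = 0.766 with an estimated correlation) and -4.47 for the mitochondrially encoded genes (adjusted p = 1.04e-07; adjusted p = 0.577 with an estimated correlation). For HFCD+FMD versus control it was 1.37 for macrophage genes (adjusted p = 3.75e-05) and 1.20 for cell proliferation (adjusted p = 9.17e-05), both with adjusted p = 0.821 with an estimated correlation.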

How the results depend on the processing

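The alternatives listed above as added were chosen after the result was seen. No paired analysis was run because the labels do not say whether a replicate number names the same mouse in both tissues. The planned division of the HFCD libraries into parts of 3 could not be run with 5 heart and 4 adipose libraries, and parts of 2 and 3 or 2 and 2 were used. The 39 adipose gene lists followed changed direction in none of the settings run, and the number of adipose genes changed by HFCD depended on which controls were kept and on the libraries high in Gm15564, whereas the heart gene counts depended on the tool, the set factor and single libraries. At least 138 of 6316 values, in at least 39 of 258 results, changed direction. At least 8 of these results had passed at an adjusted p below 0.05. No scaling moved the median of all genes by over 0.1. At the depth, spread and group sizes of these libraries together, 33 to 60 of 100 simulated 2-fold changes were called, and depth was not varied alone. Where a value below did not hold, the cause was not tested.

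Heart genes that passed for HFCD versus control (0) were 61 with DESeq2, 0 with voom, 226 with voom and quality weights and 51 with the deposited values. Those of HFCD+FMD versus HFCD (14) were 279 with DESeq2, 0 with the stricter filter, 268 with only the 2 diets, 2 with age as a covariate, 1328 with the deposited values and 0 with no set factor. Leaving out HFCD replicate 5, or replicates 3 and 5, with no set factor gave 77 and 203, and leaving out 1 library gave 0 (HFCD 5, HFCD+FMD 3) to 368 (HFCD+FMD 1), with 79, 2, 37 and 3 without control 2, 3, 4 and 6, 1 and 1 without HFCD+FMD 2 and 5, and 2, 22 and 2 without HFCD 2, 3 and 4. Genes that passed for HFCD+FMD versus control (3) were 145 with DESeq2, 1 with voom, 26 with quality weights, 1 with the stricter filter, 0 with only the 2 diets, 1193 with the deposited values, 0 with no set factor, 184 and 774 with those HFCD libraries left out as well, and 0 (HFCD 2 and 5, HFCD+FMD 2, 3 and 5) to 217 (HFCD+FMD 1) without 1 library, with 8 without control 2 or HFCD 3. In heart fits with the set factor, HFCD+FMD rested on replicate 1 alone without HFCD 5, and HFCD on replicate 5 alone in HFCD+FMD versus HFCD without HFCD+FMD 1. Gene lists with an estimated correlation were 0 in each of the 6 comparisons. Heart lists for HFCD+FMD versus HFCD (24) were 14 with no set factor, 10 and 11 with HFCD replicate 5 or replicates 3 and 5 left out as well, and 8 (HFCD 5) to 28 (HFCD+FMD 5) without 1 library. Lists for HFCD+FMD versus control (21) were 9, 12 and 12, and 7 (HFCD 5) to 26 (HFCD+FMD 1).

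Adipose genes that passed for HFCD versus control (4532) were 2247 with only the libraries low in Gm15564, of which 2115 were the same genes, and 2348 (control 1) to 4854 without 1 library, with 2991 without control 3. Those of HFCD+FMD versus HFCD (31) were 302 with DESeq2, 60 with voom, 472 with quality weights, 47 with the Gm15564 level as a covariate and 1 with only the libraries low in it. Without 1 library they were 5 (HFCD 4) to 80 (HFCD+FMD 4), with more counts given above. Those of HFCD+FMD versus control (2978) were 1916 with voom, 1834 with only the 2 diets, 1583 with only the libraries low in Gm15564, and 663 (control 1) to 3500 without 1 library, with 1164 without control 3. The share of heart genes with opposite signs for HFCD versus control and HFCD+FMD versus HFCD was 71.9% with age as a covariate. It was a mean of 56.7% (40.8% to 64.4%) with no HFCD library shared, and 44.7% (HFCD+FMD 1) to 78.7% (HFCD 5) without 1 library. At an unadjusted p below 0.01 for HFCD versus control it was 90.5% (66.5% simulated, not directly comparable). In adipose tissue the share of the genes changed by HFCD was 87.8% with age as a covariate, a mean of 79.0% (63.2% to 88.0%) with no HFCD library shared, and 83.9% (HFCD+FMD 5) to 90.8% (HFCD+FMD 4). Genes whose change differed between tissues for HFCD+FMD versus HFCD were 1 with voom.

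These heart log2 fold changes, and medians of lists, took the opposite sign. With limma voom Myh7 was 0.71 in HFCD versus control and -0.13 in HFCD+FMD versus HFCD. With voom and library quality weights the values were Nppa -1.78, Col1a1 -0.24, Ccn2 -0.54 and Dbp 0.24 in HFCD versus control, then Myh7 -0.10 in HFCD+FMD versus control. With only the libraries of the 2 diets compared the values were Col1a1 -0.0293, Ccn2 -0.17 and Dbp 0.0614 in HFCD versus control, then Cpt1b 0.11, Nppb -0.20, Myh7 -0.51 and Col1a1 -0.0736 in HFCD+FMD versus HFCD, then Nppb 0.25 in HFCD+FMD versus control. With age as a covariate Myh7 was 0.11 in HFCD versus control and -0.0929 in HFCD+FMD versus HFCD, and Nppb 0.0040 in HFCD+FMD versus control. With the deposited values Myh7 was 0.68 in HFCD versus control and -0.13 in HFCD+FMD versus HFCD. With no library set factor the values were Myh7 0.20 and Col3a1 0.14 in HFCD versus control, then Cpt1b 0.00232 and Myh7 -0.53 in HFCD+FMD versus HFCD, then Nppb 0.16, Myh7 -0.33, Dbp -0.0158 and the macrophage list 0.0782 in HFCD+FMD versus control. With set A alone Col1a1 was -0.0295, Ccn2 -0.17 and Dbp 0.061 in HFCD versus control. With HFCD replicate 5 left out and no set factor the values were Angptl4 -0.0241, Myh7 0.17, Col3a1 0.0236, Ccn2 -0.19 and Dbp 0.18 in HFCD versus control, then Bmp10 0.43, Myh7 -0.50, Ccn2 0.12, Dbp -0.20, Arntl 0.23, the complement list 0.00886 and the macrophage list 0.21 in HFCD+FMD versus HFCD, then Nppb 0.16, Myh7 -0.33, Dbp -0.0215 and the macrophage list 0.0751 in HFCD+FMD versus control. With HFCD replicates 3 and 5 left out and no set factor the values were Nppa -1.24, Col1a1 -0.25, Ccn2 -0.51, Dbp 0.20 and the atrial tissue list -0.31 in HFCD versus control, then Bmp10 0.50, Vsig4 0.18, Myh7 -0.28, Ccn2 0.43, Dbp -0.22, Arntl 0.12, the atrial tissue list 0.0371, the complement list 0.0752 and the macrophage list 0.30 in HFCD+FMD versus HFCD, then Nppb 0.16, Myh7 -0.33, Dbp -0.0206 and the macrophage list 0.0765 in HFCD+FMD versus control. Leaving out 1 library at a time gave ranges that crossed 0, with the libraries that changed the sign in brackets. These were Myh7 -0.36 to 1.68 (control 5, HFCD 2 and HFCD 4), Col1a1 -0.21 to 0.19 (control 3, HFCD+FMD 1, HFCD 3 and HFCD 5), Col3a1 -0.14 to 0.0365 (control 5, HFCD 2 and HFCD 4), Ccn2 -0.17 to 0.40 (HFCD+FMD 1, HFCD 3 and HFCD 5), Dbp -0.30 to 0.0969 (control 2, HFCD+FMD 1 and HFCD 5) in HFCD versus control. These were Cpt1b -0.42 to 0.11 (HFCD+FMD 1 and HFCD+FMD 5), Nppb -0.19 to 1.24 (HFCD+FMD 1), Myh7 -0.59 to 1.34 (control 5 and HFCD+FMD 1), Col1a1 -0.073 to 0.37 (HFCD+FMD 1), Arntl -2.20 to 0.61 (HFCD 5), the macrophage list -0.92 to 0.11 (HFCD 5), the cell proliferation list -0.31 to 0.95 (HFCD 5) in HFCD+FMD versus HFCD. These were Nppb -1.17 to 0.25 (control 4 and HFCD 5), Myh7 -0.85 to 1.09 (control 2, control 6 and HFCD+FMD 1), Col1a1 -0.0837 to 0.34 (HFCD+FMD 1) in HFCD+FMD versus control.

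These adipose log2 fold changes took the opposite sign. With limma voom the values were Ucp1 0.61 and Tnf -0.0964 in HFCD+FMD versus HFCD, then Dbp -0.12 and Arntl -0.00967 in HFCD+FMD versus control. With voom and library quality weights the values were Ucp1 0.31, Scd1 0.0513, Ccl2 -0.13 and Tnf -0.086 in HFCD+FMD versus HFCD, then Arntl -0.17 in HFCD+FMD versus control. With age as a covariate the value was Arntl -0.00126 in HFCD+FMD versus control. With the authors' deposited values the values were Ucp1 0.85 and Tnf -0.0631 in HFCD+FMD versus HFCD, then Dbp -0.13 in HFCD+FMD versus control. With the Gm15564 level as a covariate the value was Ucp1 1.76 in HFCD+FMD versus HFCD. With only the libraries low in Gm15564 the values were Ucp1 3.92, Scd1 0.0126, Ccl2 -0.0309 and Tnf -0.0652 in HFCD+FMD versus HFCD, then Arntl -0.0149 in HFCD+FMD versus control. Dbp in HFCD+FMD versus control was -7.68e-05 with RLE scaling, -0.000938 with DESeq2 and -7.09e-05 with the stricter filter. Without the mitochondrially encoded genes it was -0.00433. Ranges without 1 library that crossed 0 are given in the same way. These were Ucp1 -7.79 to 2.99 (control 1), Srebf1 -0.50 to 0.0761 (control 1) in HFCD versus control. These were Ucp1 -1.76 to 3.25 (HFCD 2), Scd1 -0.37 to 0.0434 (HFCD+FMD 4), Tnf -0.14 to 0.27 (HFCD+FMD 4), Arntl -0.34 to 0.000989 (HFCD 4) in HFCD+FMD versus HFCD. These were Ucp1 -5.91 to 2.61 (control 1), Ppargc1a -1.53 to 0.0351 (control 1), Srebf1 -0.16 to 0.41 (control 5 and HFCD+FMD 5), Dbp -0.20 to 0.18 (control 5, HFCD+FMD 1, HFCD+FMD 2, HFCD+FMD 3 and HFCD+FMD 5), Arntl -0.0444 to 0.29 (control 1, HFCD+FMD 4 and HFCD+FMD 6) in HFCD+FMD versus control.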

Other observations

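All genes and gene lists here were chosen after their values were seen. In adipose tissue HFCD shifted several lists not described above. Against control, the median log2 fold change was 0.69 for senescence (22 genes, 8 rose and 1 fell; adjusted p = 0.0259; adjusted p = 0.512 with an estimated correlation) and 0.22 for autophagy and lysosome (39 genes, 14 rose and 2 fell; adjusted p = 0.00876; adjusted p = 0.512 with an estimated correlation). It was 0.72 for inflammatory cytokines and chemokines (30 genes, 9 rose and 2 fell; adjusted p = 0.0303; adjusted p = 0.594 with an estimated correlation) and 0.21 for fibroblast and progenitor genes (22 genes, 5 rose and 0 fell; adjusted p = 0.0439; adjusted p = 0.594 with an estimated correlation). The glucocorticoid response was lower at -0.56 (24 genes, 0 rose and 6 fell; adjusted p = 0.0257; adjusted p = 0.556 with an estimated correlation), and it was as low in HFCD+FMD against control (-0.58, 0 rose and 6 fell; adjusted p = 0.000254; adjusted p = 0.596 with an estimated correlation). Other shifts were opposite in sign when HFCD+FMD was set against HFCD: reproductive tract genes went from -1.14 (8 genes, adjusted p = 0.0173; adjusted p = 0.512 with an estimated correlation) to 0.72 (adjusted p = 0.0255; adjusted p = 0.523 with an estimated correlation), and mitochondrial biogenesis and dynamics from -0.23 (31 genes, 1 rose and 11 fell; adjusted p = 0.0197; adjusted p = 0.512 with an estimated correlation) to 0.08 (adjusted p = 0.0234; adjusted p = 0.602 with an estimated correlation). Without 1 library, several of these calls ended. For HFCD against control, inflammatory cytokines were at adjusted p = 0.130 and 0.115 without control replicates 1 and 3, senescence at 0.0503 without control replicate 3, the glucocorticoid response at 0.114 and 0.0547 without control replicate 5 and HFCD replicate 1, and mitochondrial biogenesis at 0.0582 without control replicate 1. Fibroblast genes lost their call without control replicate 1 (median 0.03, adjusted p = 0.323) and without 5 other libraries. For HFCD+FMD against HFCD, reproductive tract genes lost it without HFCD+FMD replicate 5 or HFCD replicate 4 (adjusted p = 0.0966 and 0.0757), and mitochondrial biogenesis without HFCD+FMD replicate 3 or HFCD replicate 3 or 4 (highest adjusted p = 0.0917).

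Lipogenic genes fell into separate levels among the HFCD+FMD adipose libraries. In log2 CPM, Acaca was at 8.52, 8.52 and 8.42 in replicates 2, 3 and 5 but at 6.82, 6.21 and 6.04 in replicates 1, 4 and 6, against 5.79 to 6.04 in HFCD and 9.56 to 10.24 in control. Elovl6 was at 6.69, 6.61 and 6.78 in the former and at 4.83, 4.25 and 3.51 in the latter. Thermogenic transcripts were high in 1 control library only: control replicate 1 had Ucp1 at 7.03, Cidea at 5.92 and Dio2 at 4.74, and the other controls had at most -0.74, 2.02 and 1.45.

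In heart, erythroid genes were lower in HFCD+FMD than in HFCD (median -0.97, 10 genes; adjusted p = 7.82e-05; adjusted p = 0.248 with an estimated correlation) and than in control (-1.14; adjusted p = 7.47e-05; adjusted p = 0.282 with an estimated correlation), though 0 of the 10 passed alone with edgeR. Neutrophil and mast cell genes were lower by the same contrasts at -1.43 (9 genes; adjusted p = 8.25e-05; adjusted p = 0.185 with an estimated correlation) and -1.25 (adjusted p = 0.00232; adjusted p = 0.282 with an estimated correlation). None of these calls stood without HFCD replicate 5, in a fit where HFCD+FMD replicate 1 alone stood for HFCD+FMD. There erythroid genes were at -0.13 (adjusted p = 0.822) and -0.34 (adjusted p = 0.110), and neutrophil and mast cell genes at -0.16 (adjusted p = 0.752) and -0.25 (adjusted p = 0.791). Without the set factor the erythroid call against control ended (-0.40, adjusted p = 0.191). Both neutrophil and mast cell calls ended as well (-0.88, adjusted p = 0.150; -0.07, adjusted p = 0.901). With both that library and the set factor left out, erythroid genes were at -0.26 (adjusted p = 0.378) and -0.41 (adjusted p = 0.104), and neutrophil and mast cell genes at 0.04 (adjusted p = 0.774) and -0.08 (adjusted p = 0.877).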
